A study of Danio rerio with 4 samples.

How the data were processed

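Total RNA of entpd5 mutant and sibling larvae was labelled with Cy3 and Cy5 and hybridised to Agilent zebrafish arrays of 45220 spots, 43803 of them not controls, which hold 43603 different probes. Per the labels, each of 2 RNA pairs was run on 2 arrays with the dyes exchanged. Per the file headers, images were read with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name version 8.5.1.1. Per the file headers, pair a was scanned in 2 passes and annotated against Zv7, and pair b in 1 pass against Zv8. The arrays of pair a lay on slide 1 and those of pair b on slide 2.

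The deposited scanner files give red and green foreground and local background as intensity values on a linear scale, not yet normalized, with flags per spot. The files of pair b have median but no mean foreground, so the median foreground intensity was used. The plan made before the data were examined took the mean foreground, and the median where a file has no mean, and using the median on all 4 arrays, to treat them alike, was decided once the files had been seen. The deposited scanner files also give a log10 ratio of red over green from signals that the software had background-subtracted and dye-normalized, per the file headers. The deposited series table holds log2 ratios. Set against the scanner ratios, with correlations above 0.9999 and slopes of 1.00, they were log2 of mutant over sibling, with column medians of -0.01 and 0.00. On 3 arrays they differed from the scanner ratios by at most 0.005, as rounding to 2 decimals gives, and on the pair a array with mutant RNA in Cy5 by up to 0.0179. Nulls replace 12826 and 9833 values in pair a.

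No spot was saturated. Spots marked as outliers numbered 44 and 21 on the arrays of pair a and 191 and 103 on those of pair b. Between 56.2% and 68.7% of spots were well above background, depending on array and channel. Median foreground over median background ranged from 1.96 to 3.73. The spike-in controls correlated with their nominal ratios at 0.991, 0.992 and 0.991 on 3 arrays and at 0.916 on the pair b array with mutant RNA in Cy5.

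Intensities were corrected with limma's normexp method (limma 3.58.1, R 4.3.3) with an offset of 50, then normalized within arrays by loess with control spots at weight 0. Spots marked as outliers were left out, which removed 274 probes that passed the filter, and spots of one probe were averaged. Ratios were turned to mutant over sibling from the dye labels, and the 2 arrays of each RNA pair were averaged. A probe was tested if it was well above background on all 4 arrays in the mutant channel or on all 4 in the sibling channel, which left 22954. The mean of the 2 ratios was tested against 0 with limma (lmFit and eBayes, 1 residual degree of freedom, prior degrees of freedom 6.46), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. SE is the moderated standard error of that fit. The numbers that pair the RNAs come from the labels, and each array holds a mutant and a sibling RNA of one number, so the ratio is paired by construction and no separate paired fit exists. The offset draws the ratios of dim spots towards 0, and loess assumes that most probes do not differ.

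Gene names came from the scanner files of pair a and were updated through reference tables of assembly GRCz12tu. These matched 17718 probes by accession, 1259 by gene number, 1469 by symbol and 1193 by synonym, while 21964 kept the file's name. In all, 20311 probes carried a gene symbol, of 13747 different genes. In one file 11 names had been turned into dates by spreadsheet software, so names were read from the other file of the pair. Coordinates are those of the array design (Zv7). The reference tables are of another build, and none of their coordinates is given.

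The 25 gene lists, the tests and the naming rule were fixed at the same time as that plan. The lists were tested with limma's camera at the preset correlation of 0.01, 2-sided, over lists with at least 5 measured genes, with 1 probe per gene, the brightest that passed the filter, and Benjamini-Hochberg adjustment over the lists. The rule named entpd5, up to 12 genes each way that passed with one sign on all 4 arrays, filled up to 6 by genes at least 2-fold changed on each array, and from each list up to 4 members with the smallest adjusted p. All members of the phosphate and bone lists could be named. Of a gene with several probes the brightest that passed the filter was taken. No named gene was below background on every array of a genotype, so no ratio is given as a bound. Ratios of probes dim in a channel may still be drawn towards 0 by the offset. The called ctsba probe, for example, was well above background on 2 of 4 arrays in the mutant channel.

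The steps were tested on simulated arrays, made from the real intensities for the comparison of mutants with siblings, with an intensity-dependent dye bias and 200 changed probes among 22954. Of probes changed by 2 on the log2 scale, 66 of 66 were called, of those changed by 1, 67 of 67, and of those changed by 0.5, 34 of 67, all in the right direction. Of 22754 unchanged probes, 19 were called. Set against the calls of changed probes, these 19 were a larger share of all calls than the threshold on adjusted p aims at. Some of the probes called in the real data may likewise be false. Estimates were a median of 0.891 of the true change of 2. Of 25 simulated lists of 30 genes, the one shifted by 0.15 was called and 0 of the others. The simulated genes varied independently, so this does not show how camera behaves on correlated genes. In the real lists the estimated correlation was as high as 0.84, in the cell cycle list.

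The alternatives tried were no background correction, the scanner's processed signals, median centring without loess, Aquantile between arrays, no filter and a stricter filter on dim probes, and 4 arrays as independent with a dye effect. Others were an intensity trend or robust variances in eBayes, the arrays of one dye orientation, other thresholds, genes in place of probes, saturated spots left out, outlier spots kept, the deposited series table, each RNA pair left out, an estimated correlation in camera, fry, and all probes of a gene averaged. After the data had been seen, 3 more were added, the pair b array with mutant RNA in Cy5 left out, chromosome 17 left out, and the RNA pair as a random block without a dye effect. The planned random block with a dye effect could not be estimated from 4 arrays. Camera with an estimated correlation and fry rest on the 1 residual degree of freedom that 2 RNA pairs leave, so a list could hardly pass with either.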

Results

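Whole zebrafish larvae mutant for entpd5 were compared with their siblings at 7 days post fertilization on 4 two-colour microarrays. The gene entpd5 encodes an ectonucleoside triphosphate diphosphohydrolase, an enzyme that removes phosphate from nucleotides. Mutants were sorted from siblings at 6 days post fertilization by staining living larvae with alizarin red, a dye that binds mineralized bone, because mutants do not mineralize their skeleton. Each RNA came from 30 larvae. There were 2 pairs of mutant and sibling RNA, called a and b here, and each pair was hybridised with the dyes both ways round. The comparison therefore rests on n = 2 RNA pairs. Nothing in the labels says that the pairs came from separate clutches. The p-values therefore reflect only spread between these samples, which may be technical. For each probe that spread is mostly borrowed from all probes, since the fit has 1 residual and 6.46 prior degrees of freedom. The gene ifi27.2, for example, had an SE of 0.35 although its pairs spread by 1.31 (SD). The gene gnmt had an SE of 0.08 with a spread of 0.0027. The number of arrays limits the precision of every value.

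The comparison asked which transcripts differed in level between larvae that failed to mineralize and their siblings. The mutated gene gave no difference to measure. The probe for entpd5a (Zv7, chromosome 17, 41518622 to 41518681) was well above background on 3 of the 4 arrays in the mutant channel and on 3 of 4 in the sibling channel, and so was too dim for the test. Its log2 ratio of mutant over sibling was 0.09 ± 0.01 (SD, n = 2), with 0.08 in pair a and 0.10 in pair b. On single arrays it ranged from -0.06 to 0.26, a spread that averaging the dye-swapped arrays hides. The labels do not give the kind of mutation, and a point mutation need not alter the level of its transcript, so this value does not check the genotypes.

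Of 22954 probes tested, 9 differed between mutants and siblings at an adjusted p under 0.05, 1 higher and 8 lower in mutants. The one higher probe measured gnmt, the enzyme that methylates glycine from S-adenosylmethionine, which rose 2.19-fold (log2 ratio 1.13 ± 0.08, moderated SE, n = 2, adjusted p = 0.00732). It passed in 15 of 17 alternatives, and not with the scanner's processed signals (adjusted p = 0.145) or in the series table (adjusted p = 0.51, the highest of a range from 0.000105). Among the genes named by the rule that passed, the largest decrease was that of isg15, the ubiquitin-like protein induced by interferon, which fell by 2.66 on the log2 scale, with an SE of 0.19 and an adjusted p of 0.00732. This 6.33-fold decrease was found by a probe on chromosome 5 (Zv7, 15652477 to 15652536), with log2 ratios of -3.14 in pair a and -2.19 in pair b. It passed in 14 of 17 alternatives, with adjusted p from 2.33e-05 to 0.548, the highest with robust variances in limma. A second isg15 probe gave -2.21 and missed the threshold (adjusted p = 0.107). The transcript of aste1a (Zv7, chromosome 16, 29586800 to 29586859) was 2.34-fold lower in mutants, with a log2 ratio of -1.23 ± 0.11 (SE) and an adjusted p of 0.023. Its ratio was -0.43 on the pair b array with mutant RNA in Cy5 and between -1.57 and -1.39 on the others. It passed in 11 of 17 alternatives, with adjusted p from 0.000435 to 0.51, and with the arrays with mutant RNA in Cy5 alone its log2 ratio was -0.97.

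The remaining 6 probes that passed lay outside the naming rule and were singled out after their values were seen. The smallest adjusted p, 0.00081, belonged to a probe for ctsba, which encodes the lysosomal protease cathepsin B, on chromosome 17 (Zv7, 27785875 to 27785934). It gave a log2 ratio of -2.41 ± 0.11 (SE), 5.30-fold lower in mutants, and was well above background on 2 of 4 arrays in the mutant channel, while the brighter ctsba probe gave 0.24 ± 0.11 and did not pass (adjusted p = 0.772). Both probes for zgc:113984 on chromosome 25 passed, with log2 ratios of -1.13 and -0.99. They overlap (9593745 to 9593804 and 9593739 to 9593798) and so measure nearly the same stretch. The other 3 probes carry no gene symbol. They lay on chromosome 17 at 40407722 to 40407784 (log2 ratio -1.97, well above background on 2 of 4 arrays in the mutant channel) and at 40545212 to 40545271 (-1.27), and on chromosome 3 at 28753711 to 28753766 (-0.84). Whether these positions are exonic or untranslated was not determined here.

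**Figure D1:**
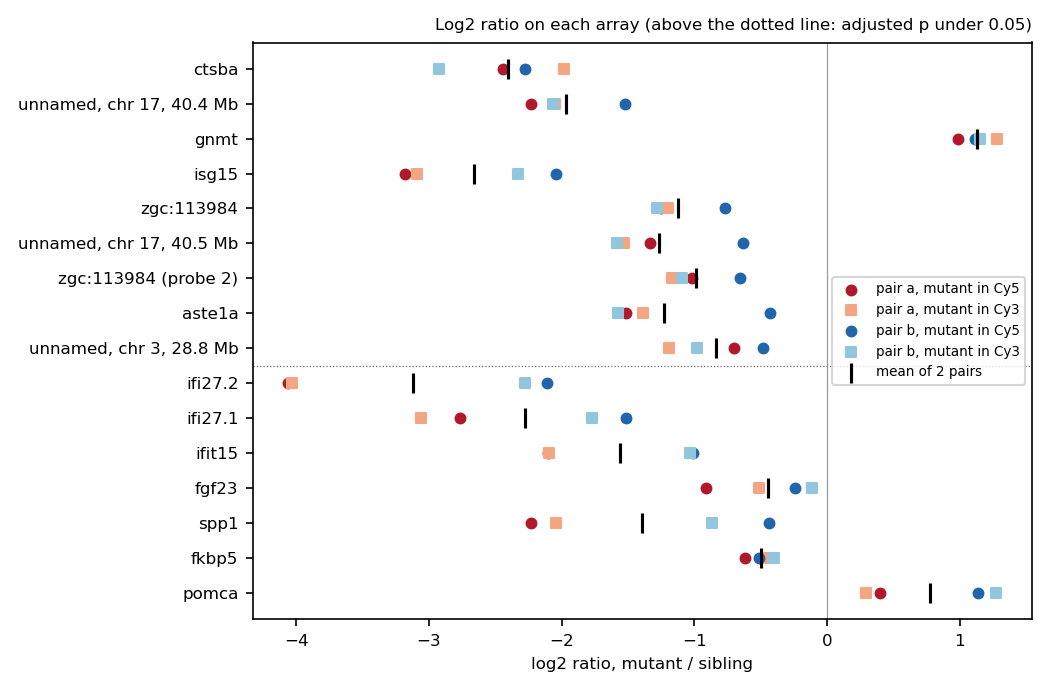
Log2 ratio of mutant over sibling (horizontal axis) on each of the 4 arrays, coloured by RNA pair and dye orientation, with the mean of 2 pairs as a black bar; the 9 probes above the dotted line had an adjusted p under 0.05. The plotted probes of isg15, ifi27.1, ifi27.2 and ifit15 were below -1 on all 4 arrays, and gnmt was above 0.98 on all 4.

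Probes with small p-values were concentrated on the chromosome that carries entpd5a. Of the 8 passing probes with coordinates in the array design, 3 lay on chromosome 17, and gnmt, whose probe has none, shares its chromosome with entpd5a in the reference tables. At an adjusted p under 0.10 there were 33 probes, 32 of them with coordinates. Of these, 17 lay on chromosome 17, where 1.18 were expected from its share of 782 of the 21145 tested probes with coordinates. The odds ratio was 30.2 (Fisher's exact test, two-sided, p = 1.28e-16). The test treats probes as independent, although all were measured in the same 2 RNA pairs. Beside entpd5a itself, the probe of coq6, a gene of ubiquinone synthesis whose probe starts 0.003 Mb away, gave a log2 ratio of -0.72 ± 0.08 (SE) and missed the threshold (adjusted p = 0.0528). On chromosome 17, 17.9% of tested probes had an unadjusted p under 0.05, against 5.97% on the other chromosomes. With chromosome 17 left out, 5 probes were called.

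**Figure D2:**
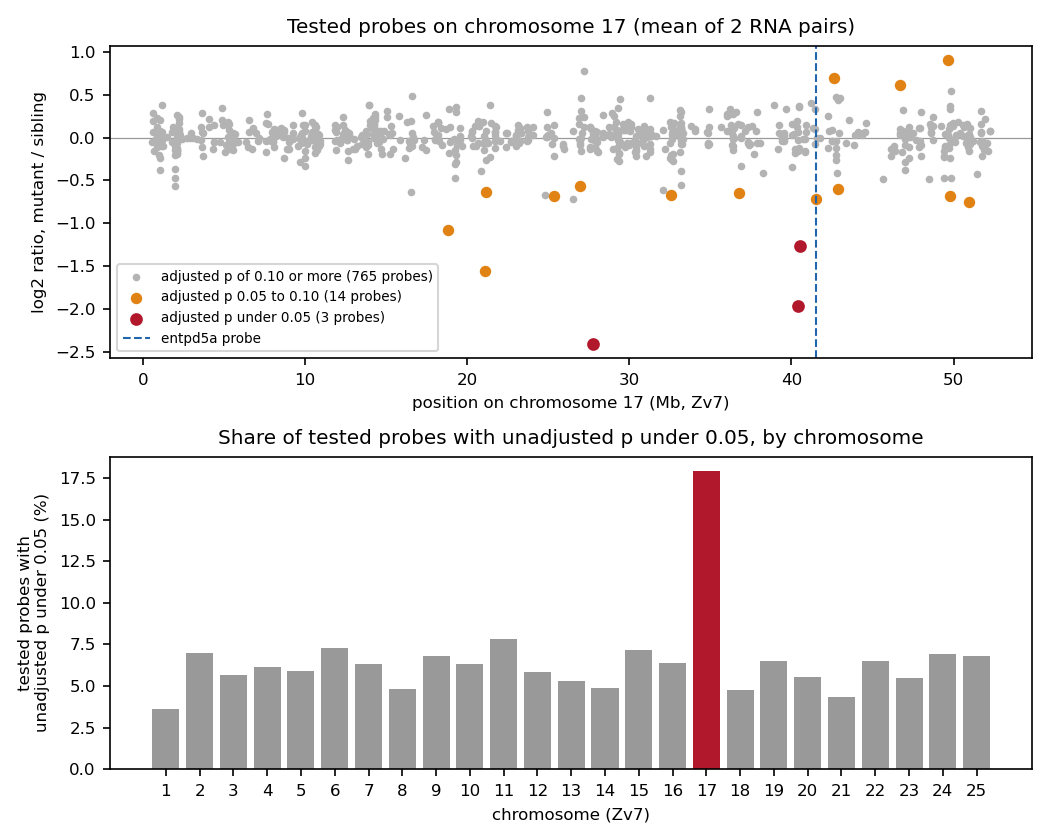
Upper panel: log2 ratio of mutant over sibling (mean of 2 RNA pairs) of each tested probe against its Zv7 position on chromosome 17 in Mb, with the entpd5a probe as a dashed line; 17 probes had an adjusted p under 0.10. Lower panel: percentage of the tested probes on each chromosome with an unadjusted p under 0.05, which was 17.9% on chromosome 17 and at most 7.80% on any other.

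Several genes that interferon induces had large negative ratios. Next to isg15, which passed, the naming rule added 3 genes that were at least 2-fold lower on all 4 arrays without passing. They were ifi27.2, with a log2 ratio of -3.12 ± 0.35 (SE, adjusted p = 0.0528), ifi27.1 with -2.28 ± 0.24 (adjusted p = 0.0517) and ifit15 with -1.56 ± 0.21 (adjusted p = 0.0859). They passed in 6 of 17, 7 of 17 and 5 of 16 alternatives, with adjusted p down to 0.000644, 0.000555 and 0.00401 with no filter on dim probes and up to 0.825, 0.825 and 0.801. In each of the 4 genes the ratio was farther from 0 in pair a than in pair b, as for ifi27.2 with -4.05 and -2.19. A second ifi27.2 probe disagreed between the pairs, at -2.43 in pair a and 0.34 in pair b. Of these genes only ifit15 lies on chromosome 17. No gene was added among those higher in mutants.

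The innate immunity and inflammation list as a whole leaned the other way. Of its 34 measured genes, 26 had positive and 8 negative ratios, and the median log2 ratio was 0.09. Camera called the list higher (adjusted p = 0.00652). The call was lost with an estimated correlation (adjusted p = 0.955), a setting with only 1 residual degree of freedom. It was also lost with no filter on dim probes (adjusted p = 0.189), with median centring (0.054), with the stricter filter (0.0711) and on the arrays with mutant RNA in Cy5 alone (0.141). Only isg15 passed over all probes, and 6 members passed when adjusted over the list alone. These included irf1b, a transcription factor of the interferon pathway, with a log2 ratio of 0.75 ± 0.09 (SE), which passed over all probes in 7 of 17 alternatives, and tnfb, a cytokine of the tumour necrosis factor family, with 0.40 ± 0.08. The antiviral gene rsad2, on chromosome 17, stood at -0.67 ± 0.16 and was well above background on 3 of 4 arrays in the mutant channel.

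In the osteoblast and bone matrix list, 33 genes were measured and none was called over all probes. Camera gave an adjusted p of 0.0665 towards lower (0.955 with an estimated correlation), and the median log2 ratio was -0.02, or 0.03 with median centring in place of loess. One member was called when adjusted over the list alone, spp1, which encodes the bone matrix phosphoprotein osteopontin. Its log2 ratio was -1.40 ± 0.28 (SE, adjusted p over all probes 0.303), with -2.14 in pair a and -0.65 in pair b, a spread of 1.05 (SD). It passed over all probes in 1 of 17 alternatives, with no filter on dim probes (adjusted p = 0.045, the lowest of a range up to 0.825). The other spp1 probes gave -1.20 and -0.44. The ratios of the osteoblast transcription factors sp7 and runx2b were 0.05 ± 0.08 and -0.02 ± 0.09. Collagen I chains col1a1a and col1a2 stood at 0.00 ± 0.08 and -0.13 ± 0.14, col1a2 with 0.18 in pair a and -0.44 in pair b. The alkaline phosphatase alpl stood at -0.06 ± 0.09.

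Of the phosphate and calcium homeostasis list, 22 genes were measured and none passed, over all probes or when adjusted over the list alone. Its median log2 ratio was 0.01, with either sign among the alternatives, its mean -0.01, and camera gave an adjusted p of 0.911. The member with the smallest p was fgf23, the hormone that promotes phosphate excretion, at -0.44 ± 0.12 (SE, adjusted p = 0.581), with -0.71 in pair a and -0.18 in pair b. It was well above background on 3 of 4 arrays in the mutant channel. Its receptor fgfr1a had a ratio of -0.26 ± 0.08, and cyp24a1, which inactivates vitamin D, one of 0.22 ± 0.08. The fgfr1a ratio was -0.34 and -0.60 on the arrays with mutant RNA in Cy5, and -0.12 and 0.03 with it in Cy3. Of other members, enpp1 had a ratio of 0.06 ± 0.08, ankha 0.11 ± 0.08, phex 0.05 ± 0.09, and the phosphate transporters slc20a1b and slc34a2a 0.16 ± 0.08 and -0.04 ± 0.08. The cartilage list (23 genes) had a median of 0.00 and the osteoclast and macrophage list (16 genes) one of 0.02, with no member called in either. The osteoclast protease ctsk stood at 0.24 ± 0.08.

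Camera called 5 more of the 25 lists, and fry, which asks whether the members of a list move one way, called none. Each of the 6 calls was lost with an estimated correlation, all with an adjusted p of 0.955. On the arrays with mutant RNA in Cy5 alone, the skin (adjusted p = 0.125), circadian (0.141) and neuron (0.688) calls were lost. A dye effect cancels only when both orientations are averaged, and 135 probes were called for dye at the same threshold. The neuron call was also lost with the processed signals (0.151) and in the series table (0.0733). Lower in mutants were the cell cycle list (48 genes, median -0.09, adjusted p = 0.000516), the digestive enzymes (25 genes, median -0.08, adjusted p = 0.000485) and the skin and keratin list (38 genes, median -0.08, adjusted p = 0.000485). Higher were the circadian clock (34 genes, median 0.09, adjusted p = 0.00225) and neuron lists (41 genes, median 0.06, adjusted p = 0.0182). No member of these 5 lists passed over all probes. When adjusted over the list alone, only 2 digestive enzymes did, the elastase cela1.4 (-0.59 ± 0.12, SE) and the amylase amy2al2 (-0.63 ± 0.13).

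In 3 of these lists the pairs took opposite signs. The median of the cell cycle list was 0.12 in pair a and -0.29 in pair b, that of the digestive enzymes -0.35 and 0.10, and that of the neuron list 0.15 and -0.01. The circadian list had similar medians, 0.07 in pair a and 0.09 in pair b, with 28 of 34 ratios positive. Its leading members were nfil3-5 (0.33 ± 0.08) and nr1d4a (0.32 ± 0.09), repressors of the clock. Over the alternatives the ratio of nfil3-5 ranged from 0.0076 to 0.66 and that of nr1d4a from 0.22 to 0.54. The skin list had medians of -0.14 and -0.02, led by the keratin krt17 (-0.38 ± 0.09) and the cornified envelope gene ppl (-0.28 ± 0.08), though its median was 0.004 with median centring in place of loess.

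**Figure D3:**
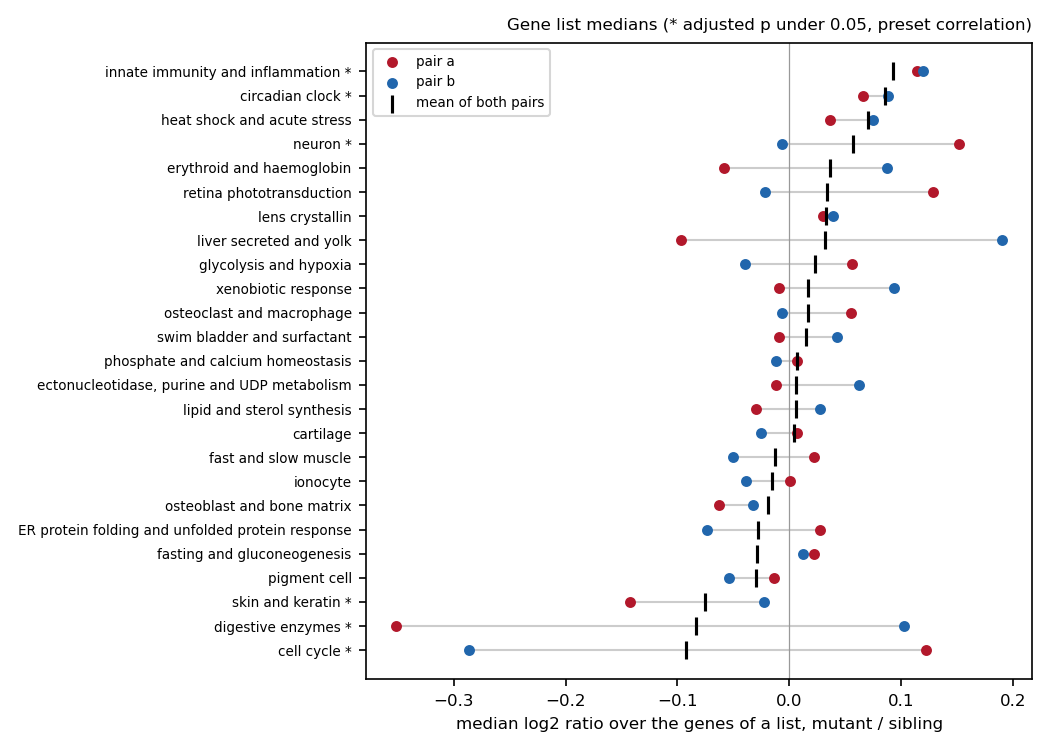
Median log2 ratio of mutant over sibling (horizontal axis) over the measured genes of each of the 25 gene lists, in pair a (red) and pair b (blue), with the median of their mean as a black bar; asterisks mark the 6 lists called by camera with the preset correlation. The digestive enzymes stood at -0.35 in pair a and 0.10 in pair b, the cell cycle list at 0.12 and -0.29.

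The other lists were not called, and for most the sign of the median depended on the pair or the normalization. In the heat shock and acute stress list (35 genes, median 0.07, adjusted p = 0.911) members went both ways, and 6 were called when adjusted over the list alone. They included the co-chaperone fkbp5 (-0.49 ± 0.08), the small heat shock protein hspb8 (-0.46 ± 0.08), the hormone precursor pomca (0.77 ± 0.18, on chromosome 17) and hsp70l (0.34 ± 0.08). In the list of ectonucleotidases and of purine and UDP metabolism (34 genes, median 0.01), xanthine dehydrogenase, xdh, on chromosome 17, was the only member called over the list alone, at 0.46 ± 0.08. The related ectonucleotidase entpd8 stood at -0.20 ± 0.08. Among 49 genes of protein folding in the endoplasmic reticulum (median -0.03) none was called; ero1a stood at 0.38 ± 0.08 and asns at -0.33 ± 0.10.

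The glycolysis and hypoxia list (25 genes) had a positive median of 0.02 and a negative mean of -0.04. Its one member called over the list alone was the enolase eno1a, at -0.51 ± 0.08, with a range from -0.74 to -0.085 over the alternatives. Of the retina phototransduction list (45 genes, median 0.03), pde6gb (0.49 ± 0.10) and the red opsin opn1lw1 (-0.46 ± 0.10) were called over the list alone, and xdh, which is also in the pigment cell list (21 genes, median -0.03), was called there too. No member was called, over all probes or over the list alone, in the lists of ionocytes (23 genes, median -0.02), fasting and gluconeogenesis (34 genes, -0.03), lipid and sterol synthesis (28 genes, 0.01), xenobiotic response (16 genes, 0.02) and lens crystallins (32 genes, 0.03). The same held for erythroid genes (22 genes, 0.04), muscle (39 genes, -0.01), swim bladder (14 genes, 0.01) and liver secreted proteins and yolk (29 genes, 0.03). In the erythroid list the median and mean were positive while camera pointed lower, and in the muscle list the mean was 0.01 while the median and camera pointed lower. Camera called the lens list higher with no filter on dim probes (adjusted p = 0.0354) and without the pair b array with mutant RNA in Cy5 (adjusted p = 0.0159).

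Across the 22954 probes, the ratios of the RNA pairs correlated weakly (Pearson r = 0.18, Spearman rho = 0.11), and 54.2% had the same sign in both pairs. Probes are not independent replicates, so no p is given. The dye-swapped arrays of one RNA pair correlated at 0.42 in pair a and 0.34 in pair b. There were 9 probes with a ratio at least 2-fold from 1 in one direction on all 4 arrays, 1 higher and 8 lower, and 0 with the sign of pair b turned. With that sign turned, limma called 0 probes, against 9, and 818 had an unadjusted p under 0.05, against 1478. Each slide held 1 RNA pair and both genotypes, so the ratios are within slides and the values of pairs a and b are the values within each slide. The number of called probes ranged from 0 to 102. The 0 was by limma in the deposited series table, where 1209 had an unadjusted p under 0.05. The 102 came from all 4 arrays in a fit with the RNA pair as a random block. In that fit the estimated correlation within a pair was -0.079, so the dye swaps counted as separate replicates although n = 2.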

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

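The test of chromosome 17 and that of a shift of the whole chromosome were set before their results were seen. The tests of single probes, of the position of interferon genes, of leukocyte markers, of further interferon genes and of glucocorticoid targets were chosen or worded after the results they bear on had been seen, and so were the 3 added gene lists, over which the p-values of camera were adjusted.

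The concentration of small p-values on chromosome 17 was large (odds ratio 30.2 among probes with an adjusted p under 0.10). The ratios of the 2 RNA pairs correlated at 0.67 over tested probes on chromosome 17 and at 0.15 over the others. Of the 17 probes, 11 lay within 10 Mb of the entpd5a probe, where 249 of 782 tested probes lie (odds ratio 4.05, Fisher's exact test, p = 0.00634). Here too the test treats probes as independent. An unadjusted p under 0.05 was most frequent at 40 to 45 Mb (33.3% of tested probes). The share also reached 24.6% at 15 to 20 Mb and 20.2% at 0 to 5 Mb. A shift of the whole chromosome is argued against, since its median differed from the others' by 0.0013. A candidate explanation is that sorting by phenotype also sorted the parental alleles linked to entpd5a, so that mutants and siblings differ in sequence along this chromosome whatever the mutation does, and whether gnmt, coq6, pomca or xdh respond to the loss of entpd5 or differ by linkage is open. Some ratios on chromosome 17 may then reflect variants under single probes. Of the 17 probes there, 5 had another tested probe of the same gene, of id2a, ankrd9, ctsba, zgc:65997 and nenf. These other probes moved by a median of 0.0067 of the change of the first, from -0.12 to 0.35. None of them measures gnmt, coq6, pomca or xdh. On other chromosomes, 4 such probes do not overlap the first, of sypl2a, dap1b (2 probes) and isg15. They moved by 0.03, 0.37, 0.50 and 0.83, a range that overlaps.

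The lower ratios of interferon-induced genes cannot all come from positions beside entpd5a, since 4 genes lower on all 4 arrays, isg15, ifi27.1, ifi27.2 and sacs2, lie on other chromosomes. A broad loss of leukocytes in the mutant pools is argued against by 32 leukocyte markers. Their median log2 ratio was -0.0233 with quartiles of -0.08 and 0.08, where the pattern needed about -0.5 or less. Of them apoeb, among the most abundant, gave -0.26 and lcp1 0.22, and 16 of the 32 are also in the lists fixed before. The median of such a list cannot exclude loss of a small subset of leukocytes. Further interferon genes, 35 measured, were lower as a list by limma's camera (adjusted p = 0.000113, median -0.06, 24 negative and 11 positive), but 0 of them passed over all probes, the smallest adjusted p being 0.357 for mxe (-1.36). Their adjusted p was 0.653 with an estimated correlation (0.42, on 1 residual degree of freedom), and their median was -0.19 in pair a and 0.05 in pair b. A stronger interferon response in the sibling pools, larger in pair a, is a candidate explanation, and whether it follows from the genotype or from how the larvae were kept after sorting stays open, since the labels do not say how.

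Another pattern was a lower fkbp5 with a higher pomca, as weaker glucocorticoid signalling might give. The median log2 ratio of other glucocorticoid targets, 29 measured, was -0.0075 with quartiles of -0.12 and 0.07, and limma's camera gave an adjusted p of 0.346, which neither shows nor excludes it. Of these, 16 are also in the lists fixed before, and the gene pomca lies on chromosome 17.

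In 7 of 183 results checked, 1 of the 4 arrays stood apart from the others. For 4 independent arrays chance gives about 5 in 100. These arrays are dye swaps of 2 RNA pairs and so not independent, and that rate may not hold for them. The pair b array with mutant RNA in Cy5 had a spike-in slope of 0.565, against 0.772 to 0.796 on the others, and a spike-in correlation of 0.916, against 0.991 to 0.992. The same array gave aste1a a log2 ratio of -0.43, against -1.57 to -1.39. The pair b array with mutant RNA in Cy3 gave mgp 0.26, against -0.08 to -0.07. The pair a array with mutant RNA in Cy3 gave rhag -0.063, against -0.45 to -0.39, and krt17 -0.71, against -0.31 to -0.23. The pair a array with mutant RNA in Cy5 gave anxa5b 0.023, against -0.17 to -0.15.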

How the results depend on the processing

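The alternatives without the pair b array with mutant RNA in Cy5, without chromosome 17 and with a random block were chosen after seeing the data. Against 9 called probes (1 higher, 8 lower), there were 26 (5 higher, 21 lower) with no background correction, 2 (0 and 2) with the scanner's processed signals, 33 (14 and 19) with median centring and 67 (20 and 47) with no filter on dim probes. The stricter filter gave 4 (1 and 3), the 4 arrays with the RNA pair as a random block 102 (40 and 62), the 4 arrays as independent 26 (9 and 17), the intensity trend 18 (3 and 15) and robust variances 6 (1 and 5). The arrays with mutant RNA in Cy5 alone gave 5 (2 and 3), those with mutant RNA in Cy3 alone 43 (9 and 34), the deposited series values 0 (0 and 0, with 1209 probes at an unadjusted p under 0.05), and leaving out chromosome 17 gave 5 (1 and 4). An adjusted p under 0.10 gave 33 (9 and 24) and genes in place of probes 2 (1 and 1). Leaving out the pair b array with mutant RNA in Cy5 gave 11. In the settings with a single dye orientation, a dye effect stays in the ratios. The causes were not tested, except that the 0.10 threshold is looser by construction, the stricter filter tests fewer probes and the chromosome 17 setting leaves out called probes. All 9 probes were also called with no background correction, median centring, no filter, the trend and the random block. The random block (correlation within a pair -0.079) and the fit of 4 arrays as independent count dye swaps of 2 RNA pairs as replicates. Aquantile leaves the log ratios unchanged and so gave the same 9. The planned random block with a dye effect was not run, as it could not be fitted to 4 arrays, and robust variances enter no camera test. No spot was saturated, so that setting changes nothing. Like Aquantile, it is counted among the alternatives without adding evidence.

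The ratio of entpd5a was 0.10 with no background correction, 0.22 with the processed signals, 0.22 in the series table, 0.056 from the arrays with mutant RNA in Cy5, 0.13 from those in Cy3 and 0.17 without the pair b array with mutant RNA in Cy5. It ranged from 0.08 to 0.10 with either pair left out. The correlation of the pairs was 0.11 with no filter on dim probes. Of the gene lists, 0 were called with an estimated correlation, 0 by fry and 2 from the arrays with mutant RNA in Cy5. With an estimated correlation and with fry, the test rests on 1 residual degree of freedom. Of the 16 alternatives with a camera test at the preset correlation, digestive enzymes and cell cycle were called in all 16. Skin and circadian clock were called in 15, neuron in 13 and innate immunity in 12. All 16 share the preset correlation of 0.01, so their number does not test it. The estimated correlation was 0.69 for digestive enzymes and 0.84 for cell cycle. The osteoblast list was called in 1, the 4 arrays as independent (adjusted p = 0.0492, range 0.0492 to 0.719), and the lens list in 2, with no filter and without the pair b array with mutant RNA in Cy5 (adjusted p from 0.0159 to 0.568 over its alternatives). With either pair left out, the median of digestive enzymes ranged from -0.35 to 0.10, that of cell cycle from -0.29 to 0.12 and that of neuron from -0.0062 to 0.15, and the skin median was 0.004 with median centring. Against 9 probes at least 2-fold changed on all arrays, there were 15 with the processed signals, 15 in the series table, 5 with median centring, 17 on the arrays with mutant RNA in Cy3, 16 without the pair b array with mutant RNA in Cy5, and 16 to 63 with one pair left out. The log2 ratios of gnmt, isg15 and aste1a kept their sign in all 19 alternatives and stayed under the threshold in 15, 14 and 11 of the 17 with a test. Of genes not called, irf1b passed in 7, fkbp5 and eno1a in 2, and spp1, hspb8, xdh and ero1a in 1. Leaving out chromosome 17 keeps gnmt, whose probe has no coordinates. Median centring without loess changed the split of calls to 14 higher and 19 lower. Median foreground over background of 1.96 to 3.73 limits what dim probes can show.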

Other observations

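Several members of the fixed lists had similar ratios in both RNA pairs without passing the test over all probes. In purine breakdown, xdh gave 0.46 in pair a and 0.45 in pair b, and its ratio lay between 0.45 and 0.47 on the 4 arrays (adjusted p = 0.164). Its probe lies on chromosome 17. The chaperone hspb8 gave -0.47 and -0.45, and fkbp5 -0.53 and -0.46.

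Named genes that nearly passed, at an adjusted p under 0.10, were looked at after their values were seen. On chromosome 17 the muscle gene actn2b stood at -1.08 ± 0.14 (SE), id2a at -0.68 ± 0.09 and nenf at -0.68 ± 0.08. A second probe gave id2a -0.0046 and nenf -0.24. Elsewhere dcaf13 stood at 1.58 ± 0.18 from one probe on chromosome 16, while 2 probes that start within a few bases of it gave -0.11 and -0.17.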
